A study of Arabidopsis halleri subsp. gemmifera and Arabidopsis thaliana with 4 samples.

How the data were processed

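Total RNA from roots grown in a hydroponic Hoagland-type solution was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. There were 4 libraries, 2 of A. halleri ssp. gemmifera and 2 of A. thaliana, grouped by species and numbered as the labels number them. The submitters' processing notes name the TAIR 10 build, and the aligner, counter, strand setting and read filters are not given in the sources used here. The deposited tables list 41671 transcript models of A. thaliana for every library, so reads of A. halleri were counted on the models of the other species. Per the file headers, the deposited values are whole-number counts of total reads and of unique reads per model, with the model's length. The deposited RPKM values, per the file headers, are reads scaled by model length and library size, and they were recomputed from the total counts, model lengths and library totals without a difference beyond rounding.

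The depth was 16335761 and 15497893 total reads in A. halleri and 18127031 and 22762183 in A. thaliana, of which 69.5% to 69.8% were unique. Reads shared between transcript models of 1 locus are not unique, and in loci with 1 model 96.2% to 97.1% of reads were. The most counted locus was a ribosomal RNA gene in both A. halleri libraries (1.06% and 1.91% of reads) and ADH1 in both A. thaliana libraries (1.29% and 1.26%). Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

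Total reads were summed over the models of each of 33602 loci. Loci were named from the annotation of TAIR10.1, in which 32835 were found, and coordinates are given on that build. Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling factors, its default filter on low counts and species as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, a common biological coefficient of variation of 0.112 and a median SE of 0.15 on the log2 scale. Levels are counts on TMM-scaled library sizes (CPM), as mean ± SD of 2 libraries. Log2 CPM values, and the log2 differences within a replicate number, used a prior count of 2. The other log2 fold changes are fitted by edgeR with its own default prior count. Where a species had 0 reads at a locus, the fold was taken against 3 reads over both libraries of that species and is a lower bound. On data simulated for this comparison with 200 changed genes, the test recovered 24.5% of 1.5-fold changes among 20565 genes, 88.5% of 2-fold changes among 20569 and 99.5% of 4-fold changes among 20541, and 0%, 4.84% and 3.40% of the calls were false. The changed genes were drawn from well-counted loci and were far fewer than the genes called in the data. The shares therefore do not give the power of the comparison itself.

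The design, the 23 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover nicotianamine, methionine supply, zinc and cadmium transport, ZIP transporters, iron deficiency, iron storage, metal chelation, copper, defensins, sulfate, aliphatic and indolic glucosinolates, phosphate, nitrogen, Casparian strip, suberin, root hair, xylem, cell division, green tissue, heat stress, jasmonate and salicylate, and reference genes. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. By limma's fry, which asks whether a list's genes moved on balance 1 way without comparing them to other genes, the iron deficiency (adjusted p = 0.0544) and xylem (adjusted p = 0.0642) lists were the ones not past 0.05. Named genes were the 8 largest rises and 8 largest falls among called genes with at least 10 reads in each library, at least 10 CPM in the higher species and no overlap between species. To these were added 12 fixed metal and nicotianamine genes, up to 4 called members per list with the largest fold and at least 10 CPM in the higher species, and the 5 loci with 0 reads in 1 species and the largest bound, of which the text gives the leading members.

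Alternatives were other scaling factors, DESeq2 1.42.0, limma on log2 of the deposited RPKM plus 1 or plus 0.1, other filters, unique reads, a test against a 2-fold change, the replicate number as a block, removal of trends on GC content and length, and leaving out each library. GC content and length were known for 99.4% of tested loci. Alternatives added after seeing the data were loci with 1 model and at least 95% unique reads, leaving out loci with 0 reads in 1 species, the older edgeR method, and summing loci of at least 90% identity over at least 80% of the shorter transcript. Shared bases between loci were found with BLAST 2.17.0 on TAIR10.1 transcripts. Because the strand setting is not given, genes overlapped by a transcript on the other strand, among them FLC, FER1, CYP81F4 and FAR1, are uncertain where both are expressed.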

Results

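RNA was sequenced from roots of Arabidopsis halleri ssp. gemmifera, a relative of thale cress that accumulates zinc and cadmium in its shoots, and from roots of A. thaliana, which does not. The title of the series concerns a root transporter of nicotianamine, a metal-binding amino acid that carries iron, zinc and copper within plants, and that transporter is not analysed here by name. Each species had 2 libraries that the labels call biological replicates, without saying how many plants or cultures each drew on. All 4 came from 1 control solution with 0.8 µM ZnSO4, 10 µM NaFeEDTA and 0.3 µM CuSO4. The libraries held 16335761 and 15497893 reads assigned to transcripts for A. halleri and 18127031 and 22762183 for A. thaliana, so that 1 read was worth between 0.0451 and 0.0634 CPM, the read count scaled to the TMM-adjusted library size. Reads of both species were counted on A. thaliana gene models, and 22649 and 22673 loci had reads in A. halleri against 23206 and 23145 in A. thaliana.

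The 2 libraries of a species were alike and the species far apart. Across genes, which are not independent replicates, log2 CPM correlated at 0.991 within A. halleri, at 0.991 within A. thaliana and at 0.703 to 0.721 between the species. The median absolute log2 difference was 0.15 between the A. halleri libraries, 0.13 between the A. thaliana libraries and 0.75 between the species means. The libraries of each species still differed by more than sampling noise, with a chi-square per gene of 9.71 in A. halleri and 12.6 in A. thaliana, so none was counted as a duplicate.

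The comparison of A. halleri with A. thaliana asks which genes, among them those for metal transport and nicotianamine, differ in roots given the same zinc, iron and copper. Most of the root transcriptome differed between the species. Of 20899 loci tested, 15215 (72.8%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 7503 higher and 7712 lower in A. halleri, and 8422 of them differed by at least 2-fold. In 87.2% of all tested loci both libraries of 1 species lay above both of the other, an order that chance gives for 33.3% of unchanged genes. The naming of the libraries set replicate 1 of both species apart from replicate 2, and 15212 of the calls had the same direction within each replicate number. Calls without overlap between the species, also 15212, must have the same direction in both, so that count does not test for a replicate effect. Reads of A. halleri that match the A. thaliana models poorly would be missed or counted elsewhere, so each fold joins expression with how well the reads matched.

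Several genes that move zinc into the xylem or the vacuole were far higher in A. halleri. HMA4 (AT2G19110, TAIR10.1 chromosome 2, 8278789 to 8286561), the pump that loads zinc and cadmium into the xylem, stood at 3760.1 ± 263 CPM in A. halleri and 150.05 ± 12.9 in A. thaliana (SD, n = 2), a 25.1-fold difference (log2 4.65, SE 0.14, edgeR adjusted p = 3.87e-07). The log2 difference of HMA4 was 4.66 within replicate 1 and 4.63 within replicate 2. HMA3 (AT4G30120, chromosome 4, 14730215 to 14733628), a vacuolar zinc and cadmium pump, was 36.1-fold higher, at 249.6 ± 7.55 against 6.88 ± 0.742 CPM (edgeR adjusted p = 1.46e-07). MTP1 (AT2G46800, chromosome 2, 19235374 to 19239577), a vacuolar zinc transporter, was 3.74-fold higher, and FRD3 (AT3G08040, chromosome 3, 2566196 to 2569700), which releases citrate into the xylem, was 12.6-fold higher. With reads unique to 1 transcript model, MTP1 and FRD3 turned to lower values in A. halleri. Each has 2 models, and of the 10991 A. halleri reads of MTP1 0 were unique, against 507 of 3578 in A. thaliana.

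**Figure D1:**
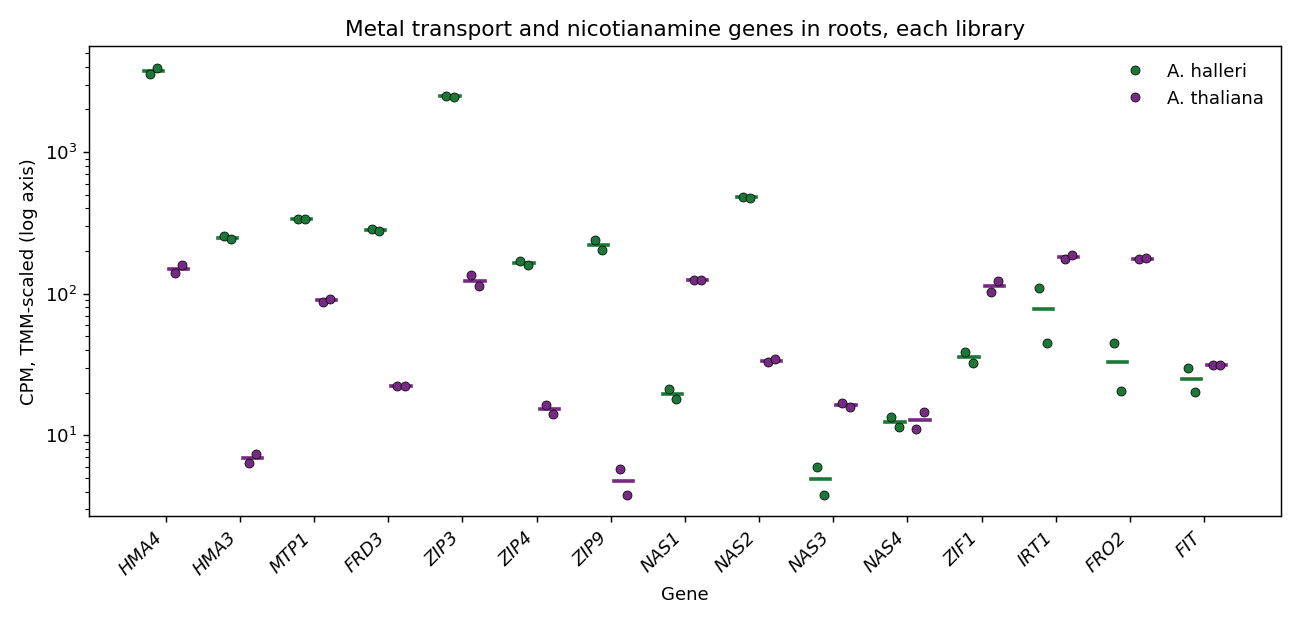
CPM on a log axis for 15 metal transport, nicotianamine and iron uptake genes, with 1 point per library (n = 2 per species) and a bar at each species mean. HMA4 lies at 3760.1 in A. halleri against 150.05 in A. thaliana, NAS1 and NAS2 lie in opposite order, and the A. halleri libraries are spread widely for IRT1 and FRO2.

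Of the 24 tested genes of zinc and cadmium transport, 11 were higher in A. halleri, 6 lower and 7 not called. The members with the largest differences went both ways. IREG2 (AT5G03570), a vacuolar transporter of iron, nickel and cobalt, had 0 reads in A. halleri and 23.4 ± 0.471 CPM in A. thaliana, at least 255-fold lower, with the floor of 3 reads taken over both A. halleri libraries. HMA2 (AT4G30110), which shares xylem loading of zinc with HMA4, was 18.5-fold lower, at 1.18 ± 0.328 against 22.2 ± 0.83 CPM. HMA4 and HMA2 share 79.2% of bases over 74.0% of the shorter transcript. HMA2 had 401 and 478 reads in A. thaliana, while HMA4 had 60613 and 62195 in A. halleri against 2483 and 3523. Reads of HMA2 counted as HMA4, with no other change, are too few for that rise. These values argue against misplaced reads of HMA2 as the whole cause of the rise of HMA4, but the fall of HMA2 stays uncertain. The list as a whole did not pass camera's test (median log2 0.44, camera adjusted p = 0.223). In the same A. halleri libraries 21 of 22 tested photosynthesis genes were also higher and 15 of 17 heat stress genes lower.

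Members of the ZIP family, importers of zinc and iron, were mostly higher in A. halleri: 9 of 14 tested rose, 4 fell and 1 was not called (median log2 2.70, camera adjusted p = 0.127). ZIP9 (AT4G33020) was 46.9-fold higher, at 221.9 ± 26.7 against 4.79 ± 1.41 CPM. ZIP3 (AT2G32270) was 19.95-fold higher and reached 2474 ± 13.4 CPM against 124 ± 16.0, and ZIP4 (AT1G10970) was 10.8-fold higher. ZIP5 (AT1G05300) went the other way, with 0 reads in A. halleri against 15.5 ± 1.89 CPM, at least 169-fold lower. ZIP5 and ZIP3 share 78.2% of bases over 63.8% of the shorter transcript.

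Nicotianamine synthase genes, which join S-adenosylmethionine into nicotianamine, changed in opposite directions. NAS2 (AT5G56080, chromosome 5, 22711141 to 22712441) was 14.2-fold higher in A. halleri, at 478.5 ± 6.79 against 33.7 ± 1.4 CPM (SD, n = 2; log2 3.82, SE 0.09, edgeR adjusted p = 1.73e-07). NAS1 (AT5G04950, chromosome 5, 1457641 to 1459039) was 6.37-fold lower and NAS3 (AT1G09240) 3.33-fold lower. NAS4 (AT1G56430) stood at 12.5 ± 1.43 against 12.9 ± 2.62 CPM and was not called (log2 -0.05, edgeR adjusted p = 0.816). The 4 genes summed to 515 ± 12.0 CPM in A. halleri and 188 ± 3.14 in A. thaliana, 2.74-fold more. NAS1 and NAS2 share 80.9% of bases over 92.9% of the shorter transcript, so the split of reads between them is uncertain.

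Transporters of nicotianamine and its metal complexes were also mixed. ZIF1 (AT5G13740), which takes nicotianamine into the vacuole, was 3.16-fold lower in A. halleri, and YSL2 (AT5G24380), of the yellow stripe-like carriers of metal complexes, was 5.39-fold lower. The other tested members of that family, YSL3 to YSL8, named after their values were seen, were all higher, from log2 0.59 for YSL5 to 1.98 for YSL8. ZIFL2 (AT3G43790), a relative of ZIF1, was 4.43-fold higher. In the list of nicotianamine synthesis and transport 8 of 15 tested genes were higher, 6 lower and 1 not called (median log2 0.59, camera adjusted p = 0.591).

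Genes for methionine and S-adenosylmethionine, from which nicotianamine is made, showed 9 of 17 higher, 4 lower and 4 not called (median log2 0.26, camera adjusted p = 0.536). ARD1 (AT4G14716), of the methionine salvage cycle, was 3.00-fold lower, SAM2 (AT4G01850) 2.94-fold higher, ARD2 (AT4G14710) 2.51-fold higher and SAM1 (AT1G02500) 2.11-fold lower. SAM1 and SAM2, both S-adenosylmethionine synthetases, share 88.2% of bases over 70.4% of the shorter transcript, which leaves their split uncertain. ARD1 and ARD2 share 93.8% over 49.0% of the shorter transcript, so their split is uncertain too. With unique reads SAM2 was no longer called (log2 0.32, adjusted p = 0.0515), but it has 2 models and kept as unique 3326 of 36950 reads in A. halleri and 3372 of 15411 in A. thaliana.

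Genes of the iron deficiency response were mostly lower in A. halleri: 14 of 25 tested fell, 2 rose and 9 were not called (median log2 -0.91, camera adjusted p = 0.0289, adjusted p = 0.817 with an estimated correlation). The transcription factors BHLH100 (AT2G41240) and BHLH38 (AT3G56970), which act in iron uptake, were 6.14-fold and 6.05-fold lower. FRO2 (AT1G01580), the root ferric reductase, was 5.35-fold lower, at 32.9 ± 17.5 against 176.2 ± 1.85 CPM, and PYE (AT3G47640), a regulator of iron homeostasis, was 4.798-fold lower. IRT1 (AT4G19690), the main iron importer of the root, was 2.34-fold lower, with 1865 and 708 reads in the A. halleri libraries against 3110 and 4125 (log2 -1.23, SE 0.34, edgeR adjusted p = 0.0135). FIT (AT2G28160), the regulator above IRT1 and FRO2, stood at 24.9 ± 6.75 against 31.3 ± 0.224 CPM and was not called (log2 -0.33, edgeR adjusted p = 0.126). The call of IRT1 was lost in DESeq2 (adjusted p = 0.067) and against a 2-fold change (adjusted p = 0.294), and the list's call without A. halleri replicate 2 (adjusted p = 0.0992), without A. thaliana replicate 2 (adjusted p = 0.0616) and with unique reads (adjusted p = 0.051). Without A. halleri replicate 1 the log2 values were -2.002 for IRT1, -3.09 for FRO2 and -0.62 for FIT, the last then called (adjusted p = 0.00623). Without A. halleri replicate 2 IRT1 was at log2 -0.72, and without A. thaliana replicate 2 those of BHLH100 and BHLH38 were -1.73 and -1.92.

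Of the genes for iron storage and iron sufficiency 2 of 7 tested rose, 2 fell and 3 were not called, and the median (log2 0.39) and mean (log2 -0.80) differed in sign (camera direction up, adjusted p = 0.856). VTL5 (AT3G25190), a vacuolar iron transporter homologue, had 2 reads in A. halleri and 1672 in A. thaliana, a ratio of 688 with a 95% counting interval of 190 to 5687. The ferritin genes FER2 (AT3G11050) and FER1 (AT5G01600) were 6.94-fold and 2.84-fold higher. Among genes of metal chelation 5 of 11 rose, 2 fell and 4 were not called (median log2 0.10, camera adjusted p = 0.427), with PCS2 (AT1G03980), a phytochelatin synthase, 3.35-fold and MT2A (AT3G09390), a metallothionein, 3.06-fold higher. PCS2 shares 85.1% of bases over 74.7% of the shorter transcript with PCS1. PCS1 was not called and had far more reads, 1406 and 1356 in A. halleri against 1768 and 2077, so the rise of PCS2 is uncertain.

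Copper homeostasis genes were split, with 7 of 17 tested higher, 7 lower and 3 not called (median log2 -0.32, camera adjusted p = 0.844). The copper importer COPT2 (AT3G46900) was 33.4-fold lower, at 0.424 ± 0.151 against 14.6 ± 4.06 CPM. The reductase FRO5 (AT5G23990) was 32.8-fold lower, with a log2 value of -5.04 that was -5.70 without A. halleri replicate 1 and -4.23 without A. thaliana replicate 1. FRO5 shares 91.4% of bases with FRO4, so its reads are not surely its own. FRO4 was not called, with 65 and 56 reads in A. halleri against 125 and 98. FRO5 had 14 and 6 against 518 and 256, so reads moved to FRO4 are too few for the whole fall.

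Genes that make aliphatic glucosinolates, sulfur-rich defence compounds built from methionine, were lower in A. halleri: 11 of 15 tested fell, 3 rose and 1 was not called (median log2 -3.24, camera adjusted p = 0.0139, adjusted p = 0.813 with an estimated correlation). The chain elongation genes MAM1 (AT5G23010) and MAM3 (AT5G23020) were 25.8-fold and 21.9-fold lower, the latter at 15.2 ± 0.441 against 332 ± 10.5 CPM. IPMDH1 (AT5G14200), a dehydrogenase of chain elongation, was 18.3-fold lower, though it shares 90.2% of bases with a relative, and MYB28 (AT5G61420), a regulator of the pathway, 17.9-fold lower. Among those that rose, named after their values were seen, the related regulator MYB29 (AT5G07690) had 29 and 23 reads in A. halleri against 0, at least 21.0-fold higher, and CYP79F1 (AT1G16410) was 11.5-fold higher with 26 and 33 reads against 4 and 2. CYP79F1 shares 88.4% of bases with CYP79F2 over 90.3% of the shorter transcript, so its reads are not surely its own. Of the indolic glucosinolate genes, which start from tryptophan, 13 of 17 fell, 2 rose and 2 were not called (median log2 -0.92, camera adjusted p = 0.0264, adjusted p = 0.813 with an estimated correlation). CYP81F4 (AT4G37410) was 5.28-fold and CYP79B2 (AT4G39950) 4.81-fold lower. PYK10 (AT3G09260), a root beta-glucosidase, was 4.31-fold higher and reached 5930.3 ± 466 CPM. The call of the indolic list was lost with unique reads (adjusted p = 0.051) and with reads of near-identical loci summed, an alternative chosen after seeing the data (adjusted p = 0.0627).

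Sulfate uptake and assimilation showed 9 of 24 tested genes higher, 9 lower and 6 not called, with a median (log2 -0.10) and mean (log2 0.06) of opposite sign (camera direction down, adjusted p = 0.856). SULTR1;1 (AT4G08620), a root sulfate importer, was 8.12-fold higher, at 214 ± 15.9 against 26.4 ± 5.39 CPM. Its relatives, named after their values were seen, went both ways. SULTR1;2 (AT1G78000) was 3.25-fold lower, at 82.7 ± 6.06 against 269 ± 2.34 CPM, and SULTR1;3 (AT1G22150) 6.74-fold higher, at 6.34 ± 0.718 against 0.952 ± 0.26. The rise of SULTR1;1 and the fall of SULTR1;2 were of similar size in CPM. SULTR1;2 shares 74.5% of bases with SULTR1;1 over 56.1% of the shorter transcript and 79.5% with SULTR1;3 over 83.1%. The split of reads among these genes is therefore uncertain. The APS kinases APK2 (AT4G39940) and APK1 (AT2G14750) were 4.37-fold and 4.24-fold lower. The 2 kinases supply activated sulfate, which glucosinolate synthesis uses. Of the phosphate starvation genes 11 of 22 rose, 9 fell and 2 were not called (median log2 0.20, camera adjusted p = 0.856). The phosphate importer PHT1;2 (AT5G43370) was 21.6-fold higher, but it shares 97.7% of bases with PHT1;1 and its count is uncertain. PHO1;H1 (AT1G68740), of the family of phosphate exporters, was 9.92-fold higher and the phosphatase PAP17 (AT3G17790) 5.65-fold lower.

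Nitrogen uptake and assimilation had 6 of 19 genes higher, 11 lower and 2 not called (median log2 -0.69, camera adjusted p = 0.385). The nitrate importer NRT2.2 (AT1G08100) was 14.3-fold higher, at 102 ± 15.3 against 7.09 ± 0.317 CPM, and its neighbour NRT2.1 (AT1G08090) was 3.43-fold lower, at 173 ± 43.6 against 592 ± 6.97. The pair shares 88.8% of bases over 92.2% of the shorter transcript, so the split between them is uncertain. The glutamine synthetase GLN1;4 (AT5G16570) was 5.93-fold higher.

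Markers of root cell types and barriers differed in several ways. Of 12 root hair genes 8 rose, 2 fell and 2 were not called (median log2 1.16, camera adjusted p = 0.138), led by RHS12 (AT3G10710) at 9.27-fold and RHS19 (AT5G67400) at 7.66-fold higher. Of 19 cell division genes 15 rose, 2 fell and 2 were not called (median log2 0.96, camera adjusted p = 0.00811, adjusted p = 0.813 with an estimated correlation). The mitotic kinase genes CDKB2;1 (AT1G76540) and AUR1 (AT4G32830) were 4.83-fold and 4.22-fold higher. Of their relatives, named after their values were seen, CDKB2;2 (AT1G20930) was not called (log2 -0.02) and CDKB1;2 (AT2G38620) was lower, with 0 and 1 reads in A. halleri against 85 and 103. CDKB1;2 shares 85.5% of bases over 68.8% of the shorter transcript with CDKB1;1 (AT3G54180). CDKB1;1 was 3.19-fold higher, at 23.9 ± 2.78 against 7.42 ± 2.15 CPM, so the split between them is uncertain. Suberin genes, which make the lipid barrier of the endodermis, fell in 9 of 17 cases, with 0 higher and 8 not called (median log2 -0.55, camera adjusted p = 0.0793). The fatty acid reductases FAR1 (AT5G22500) and FAR5 (AT3G44550) were 15.5-fold and 3.88-fold lower, and FAR5 shares 86.6% of bases with FAR8, so its reads are not surely its own. Among the alternatives, the suberin list was called only without A. halleri replicate 2 (adjusted p = 0.0306). Casparian strip genes had 2 of 9 tested higher, 6 lower and 1 not called (median log2 -0.64, camera adjusted p = 0.244), with the kinase gene SGN1 (AT1G61590) 5.19-fold lower and CASP4 (AT5G06200) 2.55-fold higher. Xylem secondary wall genes had 2 of 18 higher, 8 lower and 8 not called (median log2 -0.12, camera adjusted p = 0.427), and the cellulose synthases CESA8 (AT4G18780) and CESA4 (AT5G44030) were 2.35-fold and 1.96-fold lower.

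Photosynthesis genes, included as markers of green tissue, were higher in A. halleri roots in 21 of 22 tested cases, with 0 lower and 1 not called (median log2 2.91, camera adjusted p = 3.41e-06, adjusted p = 0.813 with an estimated correlation). PSBR (AT1G79040), of photosystem II, was 29.0-fold higher at 129 ± 25.2 against 4.45 ± 0.0309 CPM, and LHCA2 (AT3G61470), of the photosystem I antenna, was 25.5-fold higher. Chloroplast-encoded transcripts made up 0.0326% and 0.0678% of reads in A. halleri and 0.0186% and 0.0215% in A. thaliana.

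Heat stress genes were lower in A. halleri in 15 of 17 cases, with 0 higher and 2 not called (median log2 -3.05, camera adjusted p = 5.60e-05, adjusted p = 0.813 with an estimated correlation). HSP21 (AT4G27670), a plastid chaperone, was 46.2-fold lower with 4 and 21 reads in A. halleri against 640 and 776, and its log2 value of -5.53 was -4.72 without A. halleri replicate 1 and -7.19 without A. halleri replicate 2. HSP17.6A (AT5G12030), a small chaperone, was 29.0-fold lower and HSFA2 (AT2G26150), a heat shock transcription factor, 24.2-fold lower. Of the jasmonate and salicylate response genes 5 of 10 had too few reads to test, 3 rose, 1 fell and 1 was not called (median log2 1.26, camera adjusted p = 0.158). The 1 that fell was AOS (AT5G42650), at log2 -0.74 (edgeR adjusted p = 0.0345). Its call was lost in DESeq2 (adjusted p = 0.144), in limma and with the replicate block (edgeR adjusted p = 0.0509). Without A. thaliana replicate 1 its log2 value was -0.24. PR5 (AT1G75040) had 1063 and 1285 reads in A. halleri and 0 and 4 in A. thaliana, and VSP1 (AT5G24780) was 48.8-fold higher. VSP1 shares 85.8% of bases with VSP2 (AT5G24770), which was 2.39-fold higher, so the split between them is uncertain. The fitted log2 value of PR5, 9.39, was 13.2 without A. thaliana replicate 2 and 8.59 without A. thaliana replicate 1; the 13.2 is fitted against 0 reads, depends on the prior count and is no bound. Of the defensins 5 of 11 were tested, 2 higher, 2 lower and 1 not called (median log2 -0.24, camera adjusted p = 0.856), with PDF2.1 (AT2G02120) 10.4-fold lower and PDF2.2 (AT2G02100) 4.31-fold higher. PDF2.1 and PDF2.2 share 81.4% of bases over 71.9% of the shorter transcript, and both are related to PDF2.3, which was not called. The split of reads among these defensins is therefore uncertain.

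Genes often used as references were not all level. Of 11, 3 were higher, 2 lower and 6 not called, with a median of log2 -0.01 that became 0.07 with library size as the only scaling, and a mean of log2 0.05 (camera direction up, adjusted p = 0.781). UBQ10 (AT4G05320) was 2.36-fold lower in A. halleri, but turned to a higher value with unique reads, of which it had 7979 among 30625 in A. halleri and 401 among 89138 in A. thaliana. PP2AA3 (AT1G13320) was 2.00-fold higher and TIP41L (AT4G34270) 1.797-fold higher. PP2AA3 shares 87.2% of bases with PP2AA2, which had 207 and 146 reads in A. halleri against 1608 and 2084, so their split is uncertain.

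Across the 23 lists, camera with a preset correlation of 0.01 called 6, of which 2 were higher and 4 lower in A. halleri, and 0 with an estimated correlation. The counts of members were the same adjusted over the list alone, except for root hair genes (3 lower) and cell division genes (16 higher). The plot of list members shows how far the members of each list spread.

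Among genes with at least 10 reads in each library, the largest rises in A. halleri included FLC (AT5G10140, chromosome 5, 3173382 to 3179448), the repressor of flowering, at 69.8 ± 8.20 against 0.725 ± 0.0613 CPM, 94.8-fold higher. Its locus is covered by an antisense transcript. The largest was a transcribed pseudogene, AT5G44417, at 789.5 ± 29.7 against 2.32 ± 0.872 CPM, 332-fold higher. The acyltransferase gene AT2G25150 was 113-fold higher, the chitinase-domain gene AT4G19760 90.4-fold higher and FLS2 (AT5G63580), here flavonol synthase 2, 89.9-fold higher. THIC (AT2G29630), of thiamine synthesis, was 70.1-fold, GLP6 (AT5G39100), a germin-like protein, 65.9-fold and the sucrose synthase SUS3 (AT4G02280) 58.5-fold higher. AT4G19760 and GLP6 each have a copy with over 90% shared bases, so their reads are not surely their own.

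The largest fall was AT4G15390, an acyltransferase gene, at 1.63 ± 0.693 against 692 ± 98.8 CPM, 419-fold lower. The histone gene AT4G40030, from a family with very similar coding sequences, was 242-fold lower, and AT3G48450, of the RIN4 family, 102-fold lower. AT5G49440, AT4G34881 and AT3G52360, of unknown function, were 155-fold, 118-fold and 95.02-fold lower, and the transcribed pseudogene AT1G79245 was 105-fold lower. AT1G66500, a cleavage complex gene, was 93.2-fold lower, and its log2 value of -6.54 was -5.22 without A. thaliana replicate 1 and -7.23 without A. thaliana replicate 2. AT1G66500 and AT4G34881 each have a copy with over 90% shared bases, so their reads are not surely their own. The copy of AT1G66500, AT5G43620, had 1 and 2 reads in A. halleri against 1369 and 381, and so does not hold its missing reads.

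Some loci had 0 reads in both libraries of 1 species. The noncoding AT5G48412 and AT1G25098 were at least 3811-fold and 2097-fold lower in A. halleri, and the terpenoid cyclase gene AT3G29410 and the defensin-like gene AT5G33355 at least 1219-fold and 1101-fold lower. The ribosomal protein gene AT1G36240 had 0 reads in A. thaliana and 67.0 ± 0.361 CPM in A. halleri, at least 888-fold higher, with the floor of 3 reads over both libraries of a species. AT1G36240, AT5G48412, AT1G25098 and AT5G33355 each have at least 1 related locus with over 80% shared bases, so the reads could not be placed with certainty. The relatives of AT5G48412, AT1G25098 and AT5G33355 had few reads in A. halleri too. AT2G31585 had 0 and 1 against 3698 and 4360, and AT3G59930 0 and 1 against 4768 and 3334. AT1G25175 had 1 and 0 against 173 and 399, and LpxC2 9 and 4 against 1169 and 1203. These values argue against reads moved to those relatives as the cause of the 0 counts in A. halleri. The relatives of AT1G36240 had many reads and were lower in A. halleri. AT1G77940 had 1706 and 1392 against 4724 and 6302, and a locus annotated as RLK902 had 3127 and 2948 against 5027 and 6669. Misplaced reads of these relatives therefore stay open for the rise of AT1G36240.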

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

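The alternatives of single-model loci with unique reads, of loci with 0 reads in 1 species left out, of the older edgeR method and of near-identical loci summed were chosen only after the data were seen. Under the 21 alternatives, 117 named genes gave 2356 results with the same direction and side of the threshold, 29 that lost the call, 1 that gained it and 11 that reversed. The 23 lists, each run under 10 of the alternatives, gave 208, 11, 1 and 10 in the same order, the 10 being medians of uncalled lists that changed sign. The median became -0.0147 for methionine and S-adenosylmethionine supply with unique reads, and for reference genes 0.104 with unique reads and 0.0683 with library size only. Without 1 library it ranged from -0.318 to 0.270 for defensins, -0.118 to 0.0083 for sulfate, -0.317 to 0.0368 for xylem and -0.0219 to 0.0623 for reference genes. Called loci numbered 15215 in the comparison as reported and 10503 to 16030 under the alternatives other than the test against a 2-fold change, which called 6390 (3080 higher, 3310 lower) because it asks for more than a difference. The share of calls that were higher lay between 48.2% and 53.4%, and the median log2 of all genes between -0.03 and 0.08. The number of lists called fell from 6 to 0 with an estimated correlation. Without 1 library, 13686 to 14142 loci were called, the lone library then being assumed to vary like the other species, and 5 to 6 lists. With unique reads MTP1 turned to log2 -10.8 (a fitted value against 0 reads that depends on the prior count), FRD3 to -3.48 and UBQ10 to 4.67. These loci have several models and kept a minority of reads as unique, in shares that differed between the species, and the cause was not tested. NAS4, which was not called, changed sign to 0.036 with upper-quartile factors, 0.0319 with library size only, 0.0428 and 0.047 with limma on RPKM plus 1 and plus 0.1, 0.16 with GC and length trends removed and 0.17 with these and the replicate block. Without 1 library its value ranged from -0.23 to 0.18. Its values stayed near 0 throughout, and the cause was not tested. Over the alternatives run for each (20 for IRT1 and SAM2, 21 for FIT and 10 for each list), the adjusted p ranged from 3.40e-05 to 0.294 for IRT1, from 1.13e-42 to 0.0515 for SAM2 and from 0.00623 to 1 for FIT, and for the lists from 0.00624 to 0.817 (iron deficiency), 0.0191 to 0.813 (indolic glucosinolates) and 0.0306 to 0.813 (suberin). The highest values came from the test against a 2-fold change for IRT1 and FIT, from unique reads for SAM2 and from the estimated correlation for the lists. Same-numbered libraries did not deviate together (r = -0.05 across genes), which does not show whether they shared a run, and the replicate block moved the number of called loci to 14920, or to 14937 with GC and length trends removed. The alternative of exon against gene reads was not run, because 1 kind of total was analysed here. With 200 simulated changes, drawn from well-counted loci, 24.5% of 1.5-fold differences were recovered. The simulated changes were far fewer than the loci called in the data, so that share does not give the power of the comparison itself.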

Other observations

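The genes and families in this paragraph were chosen after their values were seen. The zinc deficiency regulators BZIP19 and BZIP23 differed in opposite directions, BZIP19 (AT4G35040) 2.92-fold lower and BZIP23 (AT2G16770) 2.85-fold higher in A. halleri. In the iron deficiency list MYB10 (AT3G12820) was 10.2-fold and the peptide gene IMA1 (AT1G47400) 7.17-fold lower, while BHLH101 (AT5G04150), at 1.097 ± 0.116 against 0.453 ± 0.00174 CPM, was higher and IMA3 (AT2G30766) was not called. MYB10 had 18 and 7 reads in A. halleri against 116 and 198, with a log2 difference of -2.51 within replicate 1 and -4.03 within replicate 2. ADH1 (AT1G77120), the alcohol dehydrogenase of low-oxygen metabolism, was 3.75-fold lower, at 3500 ± 517 against 13138 ± 235 CPM. Polyubiquitin genes went opposite ways: UBQ3 (AT5G03240) was 60.8-fold lower, at 75.7 ± 7.73 against 4606 ± 353 CPM, and UBQ13 (AT1G65350) had 3329 and 3053 reads in A. halleri against 1 and 1 in A. thaliana. How reads were placed among these genes was not tested. Of 89 families named in the annotation with at least 20 tested members, camera called 2. Cysteine and histidine-rich C1 domain proteins were lower in 76 of 121 tested members and higher in 32 (median log2 -1.58, camera adjusted p = 0.0138), and leucine-rich receptor-like kinases higher in 16 of 23 and lower in 1 (median log2 0.61, camera adjusted p = 0.0256). With an estimated correlation both had an adjusted p = 0.897. Some C1 domain members, among them AT5G40590 and AT4G14980, had 0 reads in A. halleri and 40.2 and 38.5 CPM in A. thaliana. How far poor matching of A. halleri reads to the models adds to the fall of that family was not tested. The MATE family of FRD3 had 23 of 45 members higher and 16 lower (camera adjusted p = 0.516), and the major facilitator family of ZIF1 49 members higher and 32 lower (camera adjusted p = 0.376).

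In the patterns that follow, the tests of the NAS genes, that of the stromal enzymes and the repeat on single-model loci were chosen only after the result was seen. Some related genes differed in opposite directions, as NAS1 and NAS2, NRT2.1 and NRT2.2 or SAM1 and SAM2 did; random pairs of called genes did so in 50.04% of cases on average. If reads of A. halleri were assigned to the wrong copy, opposite pairs should be most frequent among the closest copies. They were less frequent, 31.3% of 275 pairs of called genes at 90% identity or more over at least 80% of the shorter transcript, against 43.8% of 1200 pairs at 70 to 80% (Fisher's exact test, two-sided, p = 0.000139; 41.3% of 714 pairs at 80 to 90%, where the NAS and NRT2 pairs lie, p = 0.294), and 28.3% of 60 against 42.0% of 759 in single-model loci with unique reads (Fisher's exact test, two-sided, p = 0.041). Reads of NAS1 counted as NAS2, with no other change, would leave the sum of the 4 NAS genes level, but the sum was higher in A. halleri by at least log2 1.41 in each pair of 1 library per species, while the CPM gained by NAS2 was at least 4.09 times that lost by NAS1 and leaves room for the whole fall of NAS1. The NAS values argue against misplaced reads as the whole cause of the rise of NAS2, but not for the fall of NAS1, which stays open. The shares of opposite pairs cannot decide the question for pairs at 90% identity or more. Reads split evenly between copies would also push copies the same way, and a gene can enter several pairs, which the test takes as independent. Those pairs, other pairs at 80 to 90% and any single pair, such as PHT1;1 and PHT1;2, stay open. So does a difference between the species, which was not tested further.

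Photosynthesis transcripts were higher in A. halleri roots, and shoot RNA in those samples is a candidate explanation. Leaf RNA would bring the stromal enzymes, which are abundant there, along with the antenna proteins. The stromal sum (4 Rubisco small subunit genes, Rubisco activase and carbonic anhydrase) was 24.0 ± 8.63 CPM in A. halleri and 12.8 ± 0.177 in A. thaliana, a rise of at most log2 1.24 in any pair of libraries. The 17 antenna and photosystem genes had a median of log2 3.16, and summed to 618 ± 118 against 80.6 ± 4.18. The stromal sum thus rose less than the antenna and photosystem genes did. No leaf profile was used to say how much stromal signal shoot RNA should bring, so that cannot decide. Chloroplast-encoded reads were also higher in A. halleri (0.0326% and 0.0678%) than in A. thaliana (0.0186% and 0.0215%). Shoot RNA stays open, as do plastid development in roots, for example by light on the roots, which was not tested, and a species difference.

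Loci with 0 reads in 1 species and at least 10 CPM in the other were more frequent for A. halleri, 94 against 34 in A. thaliana (exact binomial test, two-sided, p = 1.09e-07). That is consistent with A. halleri reads failing to align to the A. thaliana reference, but genes missing from A. halleri, or models that exist only because the reference is A. thaliana, would give the same imbalance. IREG2 and ZIP5, with 0 reads in A. halleri, are among these loci. A near-identical locus, of at least 90% identity, that was higher in A. halleri was found for 0 of these 94 loci, which allows up to 3.19%. Among other loci it was found for 93 of 12469, or 0.746% (Fisher's exact test, two-sided, p = 1). With so low a share a count of 0 is likely in either case, so the test cannot decide whether reads were drawn to a copy. More distant relatives were not covered. IREG1, which shares 81.6% of bases with IREG2, and ZIP3, which shares 78.2% with ZIP5, were higher in A. halleri (log2 1.75 and 4.32). Misplaced reads were therefore not tested for IREG2 and ZIP5.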
